A study of Rattus norvegicus with 6 samples.

How the data were processed

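RNA sequencing was analysed from 6 libraries of rat bone marrow mesenchymal stromal cells, 3 from untreated control cultures and 3 from cultures kept with the AAT-ZCG hydrogel. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. The sources used here do not give strandedness, poly(A) selection, aligner or counting tool.

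The authors deposited 1 table of raw counts per gene for the 6 libraries and 1 table of FPKM values per library, per the file headers. The counts are whole numbers with no normalization. The FPKM values deposited by the authors are those counts divided by the library's summed counts and by a gene length. For the 21162 genes with a count, the length implied by counts and FPKM differed between libraries by a relative 8.79e-07 at most, over the 19429 genes with counts in at least 2 libraries. The FPKM files therefore hold the same reads as the counts, with no correction for RNA composition, and they supplied the gene lengths used here. Genes are listed by identifiers that all begin with ENSRNOG, the Ensembl prefix for rat, and the labels name rat as the organism. The submitters' processing notes list the mouse builds GRCm38 and mm10, so the genome behind the counts is not settled and no coordinates are given.

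The files do not pair identifiers with gene names, and the gene table used here lists no Ensembl identifiers, so 0 of the 30452 could be matched to a name. Genes are therefore reported by identifier, as classes of abundance and length, and without gene functions. The 39 gene lists and 8 osteogenic genes fixed before the data were examined were not analysed here, nor were the shares of mitochondrially encoded and ribosomal protein genes, because all of these need gene names.

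Genes were compared between groups with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with default settings, libraries were scaled by TMM, and the quasi-likelihood F test was fitted on the counts with group as the term. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and separately with an estimated fold change above 2 or below 0.5, the fold limits in the series' design text. The filter kept 14715 genes, which held 99.96% of all counts. Fold changes are hydrogel over control. Standard errors were taken from the fold change and its F statistic. CPM values are scaled by TMM, and log2 CPM values used a prior count of 2. The named identifiers follow a rule fixed before the data were examined, with its condition on gene symbols dropped. It takes the largest fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the groups' libraries. The first 2 in each direction are given.

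Library totals ranged from 30601703 to 93728651 counts, so a gene at 1 CPM rests on about 31 to 94 counts per library. The biological coefficient of variation was 0.081 over both groups. All 6 pairs of libraries within a group differed beyond counting noise, with a chi-square per degree of freedom from 6.49 to 18.0, so each library counted as 1 replicate. No label says that the libraries came from separate cultures or animals. The p-values then measure only the spread between these samples, which may be technical.

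The labels number the samples 1 to 3 in each group without a shared animal, litter or day, so the main comparison was unpaired. The correlations of same-numbered libraries' deviations from their group means were 0.022, 0.051 and 0.013. These were low, though each control library correlated best with the hydrogel library of its own number. The deep libraries are numbered 2 in both groups, and this difference in depth was treated as a possible batch.

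The test was checked on counts simulated for 14715 genes at the real library sizes, with 200 genes changed. Of 100 genes changed 1.5-fold, 61 were recovered, and of 100 changed 2-fold, 86 were recovered, with 8 calls among the unchanged genes. The filter kept 14384 of the simulated genes. The simulation used the fitted dispersion trend in both groups and changed far fewer genes than were called in the data. Its recovery and false calls need not hold for the data. Alternatives fixed before the data were examined were DESeq2 1.42.0, other scalings and low-count filters, a robust fit, limma 3.58.1 on log2 FPKM, a replicate block, other thresholds and leaving out each library. Alternatives added after seeing the data were thinning all libraries to the smallest total, using libraries 1 and 3 of each group alone, scaling without the 20 most abundant genes, and removing a smooth trend on gene length with a loess span of 0.5.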

Results

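Transcript levels were measured by RNA sequencing in rat bone marrow mesenchymal stromal cells, the adherent marrow cells that can give rise to bone, cartilage and fat cells. The cells came from osteogenic differentiation cultures. They were either left untreated (control, n = 3) or cultured together with the AAT-ZCG hydrogel (n = 3), an enzyme-linked material developed for bone defects in diabetes. The abbreviation is used as the labels give it. The control libraries held 35554114, 93728651 and 38785848 counts and the hydrogel libraries 31197243, 80675158 and 30601703. A difference in mean total was not detected by an exact two-sided permutation test (p = 0.5, where 0.1 is the smallest p that 3 against 3 libraries allow). Of the 30452 genes listed, 9290 had no count in any library. Between 17538 and 19261 genes had a count in a given library, with the highest numbers in the deepest library of each group.

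The libraries separated by treatment. The first principal component of log2 CPM held 57.7% of the variance and placed the 3 control libraries between -33.8 and -31.1 and the hydrogel libraries between 21.1 and 46.3. The second held 15.4% and mainly spread the hydrogel libraries, from -32.2 to 27.1. Replicates varied more with hydrogel than in controls, with biological coefficients of variation of 0.093 and 0.071, a difference that was not tested.

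**Figure D1:**
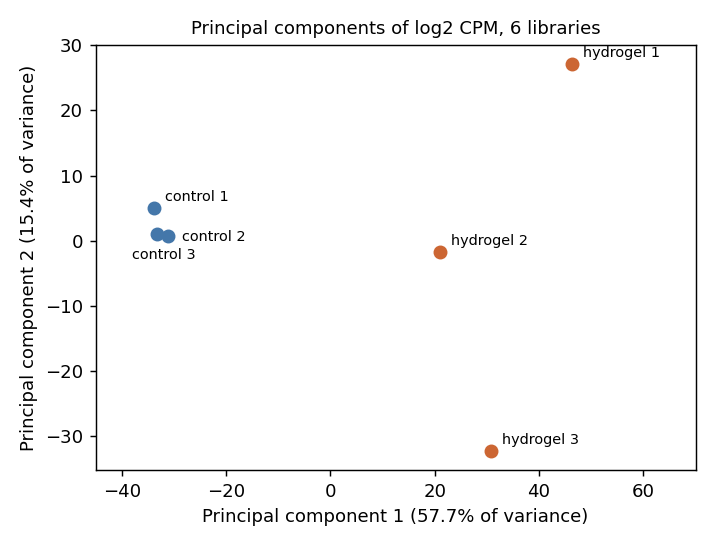
Scores of the 6 libraries on the first (x axis) and second (y axis) principal components of log2 CPM over 14715 genes, with the percent of variance on each axis. Each point is 1 library. The 3 control libraries lie together at -33.8 to -31.1 on the first component, and the 3 hydrogel libraries lie apart at 21.1 to 46.3.

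The comparison implied by the design asks which genes changed when stromal cells were cultured with the hydrogel. Co-culture was accompanied by a broad change of mostly small size. Of 14715 genes tested, 5079 (34.5%) changed at an adjusted p under 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg). Rises and falls were nearly equal in number, with 2570 genes higher and 2509 lower with hydrogel. This balance varied with the scaling. RLE size factors gave 2557 higher and 2525 lower and upper-quartile scaling 2708 and 2405, while library totals alone gave 2335 and 2929. The median absolute log2 fold change of the called genes was 0.39, and 83.4% of them changed by less than 2-fold. All 3 hydrogel libraries lay above or below all 3 controls for 6957 tested genes, or 47.3%, against the 10% that chance gives for 3 against 3. Within the shallower libraries, numbers 1 and 3 of each group, 3405 genes were called, of which 3327 were also called in the same direction with all 6 libraries. The shallower libraries are among the 6, so this overlap is not an independent replication. The deep libraries, 1 per group, allow no test on their own.

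Larger changes leaned towards rises. At a fold change above 2 or below 0.5, 843 genes were called, 531 higher and 312 lower with hydrogel. The libraries of the groups did not overlap for 519 of the 531 and for 308 of the 312. These genes were called on the same libraries, so rare overlap follows largely from the selection. Above 4-fold, 102 genes rose and 46 fell. With an unadjusted p under 0.05 and the same fold limits, as the series' design text words its threshold, 974 genes passed, 626 of them higher and 348 lower. The test on FPKM values called fewer genes past 2-fold. With a pseudocount of 1 it called 190, 113 higher and 77 lower, on a log2(FPKM + 1) scale that understates the change of low genes.

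The genes that changed over 2-fold were mostly of low abundance. Of the 843, 714 (84.7%) had a mean under 10 CPM, 456 of them higher and 258 lower with hydrogel. Of all 14715 genes tested, 5979 lay under 10 CPM. Among the 1947 genes tested under 1 CPM, 191 rose and 58 fell, all of them by over 2-fold. At low counts mainly large estimates pass the test, so the lean to low abundance was not separated from its power. Of the 1731 genes at 100 CPM or more, 1012 (58.5%) changed, but 21 changed by over 2-fold. Of the 7005 genes between 10 and 100 CPM, 1218 rose and 1453 fell. The share of genes called increased with abundance, from 12.8% under 1 CPM to 73.9% at 1000 CPM or more, as did the number of counts behind each test.

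The 20 most abundant genes took 20.3% ± 0.05 of counts in controls and 21.3% ± 0.04 with hydrogel (SD, n = 3). The hydrogel libraries were all higher, and the exact two-sided permutation p was 0.1, the smallest possible. Of these 20 genes, 8 rose, 6 fell and 6 were not called, with log2 fold changes from -0.70 to 0.74. None of them changed by 2-fold or more.

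Rising genes were shorter than falling ones. The gene length used for FPKM had a median of 2752.5 bp in the 2570 rising genes (interquartile range 1718 to 4177.5), 3186 bp in the 2509 falling genes (2167 to 4664) and 2640 bp in genes not called. The mean log2 length of rising genes was lower by 0.27 (permutation test over genes, two-sided, p = 1e-05, the smallest that 100000 permutations can give, and 1e-05 after Benjamini-Hochberg adjustment over 2 tests). Among genes changed over 2-fold the difference was -0.44 (permutation p = 1e-05, adjusted 1e-05). Genes are not independent replicates, so these values describe the 6 libraries. Of the 279 called genes under 1000 bp, 221 rose and 58 fell, a rising share of 79.2% (95% exact binomial interval 74.0 to 83.8%). With a smooth trend on gene length removed from each library, the share was 43.8% (37.8 to 49.9%). The removal centres fold changes within each length, so this drop was built in and decides nothing about its cause. Across all tested genes, the rank correlation of log2 fold change with length was weak (Spearman rho = -0.08).

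**Figure D2:**
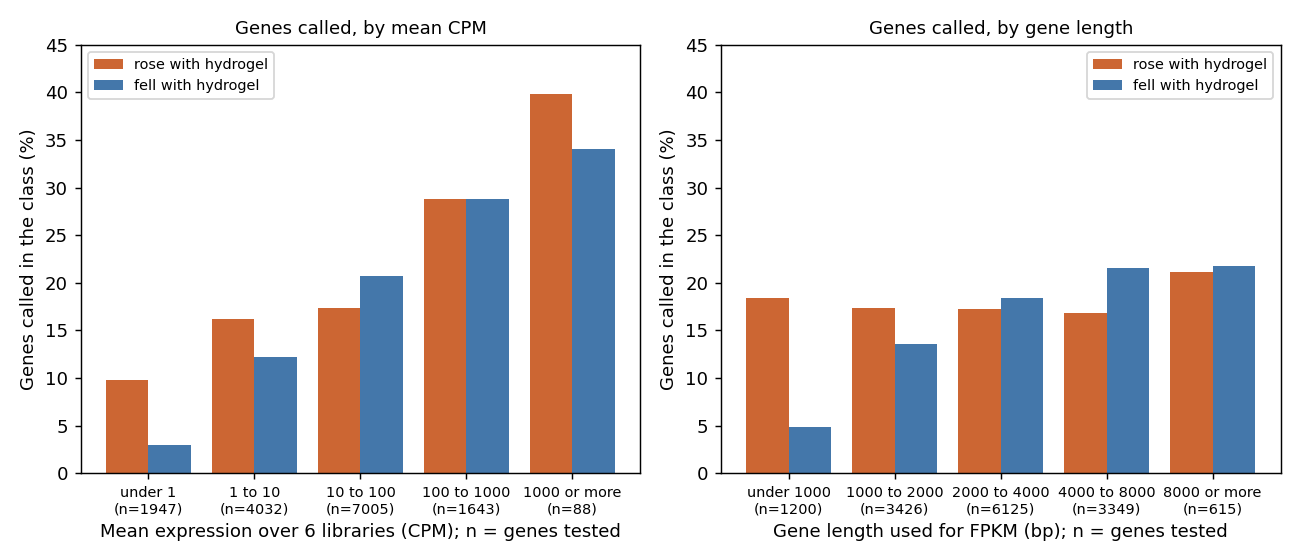
Percent of tested genes called higher (orange) or lower (blue) with hydrogel at an adjusted p under 0.05, by mean CPM over the 6 libraries (left) and by gene length in bp (right), with the number of genes tested under each class. The called share rises with abundance, and below 1000 bp 221 genes rose against 58 that fell.

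The identifier with the largest rise under the naming rule was ENSRNOG00000062858, a gene of 1528 bp. It increased from 1.14 ± 0.082 to 10.3 ± 2.66 CPM (SD, n = 3), a 9.05-fold difference of the means. Its log2 fold change was 3.17 (SE 0.21, edgeR adjusted p = 1.16e-08). ENSRNOG00000008478, of 2602 bp, increased from 5.99 ± 0.73 to 34.5 ± 6.99 CPM, with a log2 fold change of 2.52 (SE 0.14, edgeR adjusted p = 1.68e-09). The largest fall was that of ENSRNOG00000062678, of 2097 bp, from 18.6 ± 0.15 to 2.35 ± 0.48 CPM, with a log2 fold change of -2.94 (SE 0.14, edgeR adjusted p = 2.69e-10). ENSRNOG00000029055, of 3324 bp, fell from 5.64 ± 1.36 to 0.87 ± 0.19 CPM, with a log2 fold change of -2.67 (SE 0.24, edgeR adjusted p = 5.09e-07). These 4 were the extremes of 151 rising and 139 falling genes that met the rule. Whether any of them shares reads with a related gene was not examined.

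**Figure D3:**
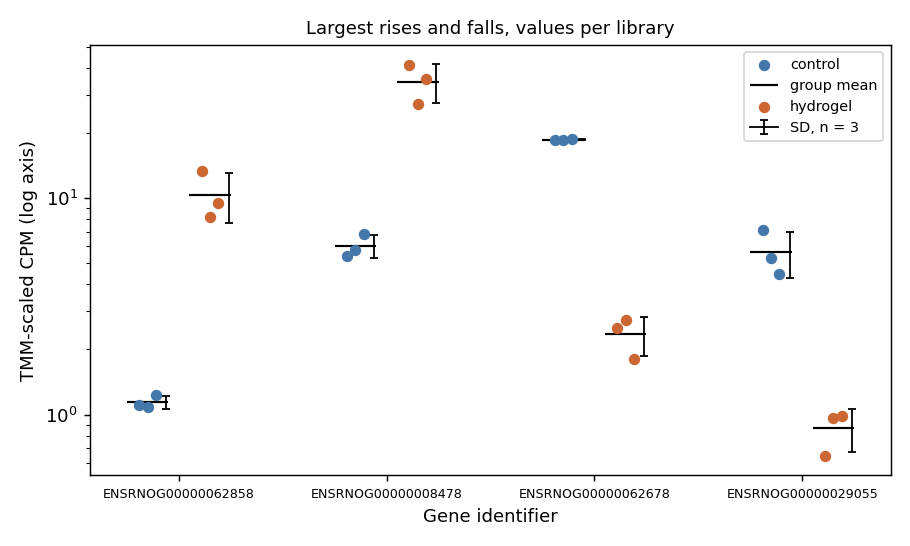
TMM-scaled CPM on a log axis (y axis) of the 2 identifiers with the largest rise and the 2 with the largest fall under the naming rule (x axis). Points are single libraries (blue, control; orange, hydrogel), horizontal lines are group means and bars are the SD of 3 libraries. The groups do not overlap for any of the 4, as the naming rule requires.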

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

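The fits on libraries 1 and 3 alone, on thinned libraries, without the 20 most abundant genes in the scaling and with the length trend removed were chosen after seeing the data. Over all alternatives, 121 of 132 counts of called genes stayed within 1.5 times the main count. Leaving out 1 library gave 3977 (without control 2) to 4695 (without hydrogel 2) changed genes, against 5079. DESeq2 called 5000, of which 4885 were called in the same direction by edgeR. With the sample number as a replicate block, 5246 genes were called, 4981 of them as in the unpaired fit. Each control library correlated best with the hydrogel library of its own number, at 0.051 or less, which is a hint and not part of the design. Over 2-fold the block called 828 genes, 808 of them as in the unpaired fit. Fits on FPKM called fewer genes over 2-fold. Limma on log2(FPKM + 1) called 190 genes (113 higher, 77 lower) in place of 843. It called 181 (105 and 76) with no filter and 425 (237 and 188) with a pseudocount of 0.1. The 190 and 425 come from the same 11987 genes and differ only in the pseudocount, which shrinks low genes by construction. Unit, test, scaling and filter changed together in the rest of the drop, whose cause was not tested. The unfiltered FPKM fit called 1708 rising genes at any fold, against 2570. A test against a 1.5-fold change called 348 rising genes in place of 531. The excess of rises over 2-fold held its direction in all settings, and the near-equal split at any fold ran from 42.8% rising (FPKM, pseudocount 0.1) to 52.96% (upper-quartile scaling). The 4 named identifiers kept direction and call in all 21 alternatives run on each, but not size. With log2(FPKM + 1), ENSRNOG00000062858 went from 3.17 to 2.11, ENSRNOG00000008478 from 2.52 to 2.07, ENSRNOG00000062678 from -2.94 to -2.24 and ENSRNOG00000029055 from -2.67 to -1.10 in log2. The gene list alternatives were not run, since the lists need gene names. After thinning to the smallest total, 75.5% of the calls under 1 CPM were kept, against 91.5 to 98.5% in the classes above.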

Other observations

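The tests with thinned libraries, with the length trend removed, of mixed RNA and of the share of the 20 most abundant genes were chosen after the main comparison had been seen. Their deciding bounds were set before each was run, except for the abundant genes, whose shares were already known. The response to the hydrogel differed in size between its libraries. On genes called over 2-fold without the library in question, at 5 CPM or more, hydrogel library 1 moved 1.19 times as far from the controls as the other two hydrogel libraries (170 genes), library 2 moved 0.83 times as far (249 genes) and library 3 0.92 times (219 genes). Control libraries treated alike gave -0.01 to 0.06. No test between single libraries is possible.

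The number of changed genes was weighed against chance and 3 technical explanations. Of the 10 splits of the 6 libraries into 3 and 3, 1 gave as many genes, the real one with 5079. The highest of the other splits gave 0 by edgeR (293 at an unadjusted p under 0.05, against 6434 in the real split). Each of those splits had libraries of both treatments on both sides. A treatment difference therefore entered their spread and held their counts down, so they do not measure chance. In addition, 10 splits are too few for a share under 0.05, and chance was not decided. Thinned to the smallest library, the data still called 93.0% of the genes in the same direction. Each group had 1 deep library, so thinning could hardly remove a group difference. It shows only that most calls did not need the extra depth. With the length trend removed, 93.3% were kept, 2252 of 2570 rises and 2485 of 2509 falls. The trend was small beside most called changes, so a high share was likely from the start. The split moved to 2289 higher and 2991 lower. The removal also re-centred each library's level, which acts like a change of scaling. The shift in balance therefore cannot be credited to the length trend alone. The share of the 20 most abundant genes can shift all other genes by a log2 of at most 0.019 between a control and a hydrogel library, against a lower quartile of 0.258 for the absolute log2 fold change of called genes, which argues against a distortion by those genes. A difference between cultures or preparation days that followed the groups stays open, since the labels give none.

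The larger response of hydrogel library 1 than of hydrogel library 2 was weighed against depth and mixed RNA. After thinning to equal totals the gap between their ratios was still 0.36. Thinning leaves the expected CPM unchanged, and genes at 5 CPM or more keep many counts, so little movement was likely from the start. The result shows only that the gap did not need the extra counts of library 2. A batch that goes with the deep libraries stays open. Each ratio rests on its own genes and has the other library in its reference. The gap therefore counts their difference from both sides and is not a direct response size. If control-like RNA had been mixed into library 2, rising and falling genes would give 1 fraction. On genes chosen in library 3, the fraction was 0.278 (95% bootstrap interval over genes 0.239 to 0.333) for 156 rising genes and 0.121 (0.099 to 0.146) for 146 falling genes. The difference was -0.157, which mixing alone would not give. Genes are not independent replicates, so the intervals may be too narrow. With 1 library set against 1 other, variation between single libraries could also part the fractions, so mixing was not excluded. What made the response of library 1 larger stays open, and no biological explanation was tested, since the labels name no difference between the 3 hydrogel libraries.

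The excess of rises among short genes may come from a length-dependent yield. With a smooth trend on gene length removed from each library, the rising share of called genes under 1000 bp went from 79.2% to 43.8%. The removal centres fold changes within each length, so a fall of this share was built in and does not decide for or against the trend. For the genes under 1000 bp called over 2-fold, the rising share was 86.7% (65 of 75). It was 76.5% (52 of 68, 95% exact binomial interval 64.6 to 85.9%) after the removal. The trend was small beside a 2-fold change, so its removal could turn few of these genes around and decides nothing here. Over all lengths, 63.0% of genes called over 2-fold rose before the removal and 59.8% after it. Low abundance was not separated from length: under 1 CPM, 191 genes rose over 2-fold and 58 fell. Slopes per doubling of gene length were fitted to each library's deviation from the gene's mean log2 CPM over the 6 libraries. They were 0.014 to 0.026 in the 3 controls and -0.036 to -0.008 in the 3 hydrogel libraries. Such deviations cancel over the libraries, so group means of opposite sign are built in. The correction also moved the median log2 fold change of all tested genes under 1000 bp from 0.13 to -0.06. It removes a true rise of short genes as readily as a technical one. A length-dependent yield and a response of short transcripts to the hydrogel cannot be told apart, because both follow the groups.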
